A study of Mus musculus with 6 samples.

How the data were processed

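RNA was measured in 6 libraries of GT1-7 cells, 3 after 24 h with 0.125 µM Alisol B and 3 controls, all after 12 h without serum. Total RNA was extracted with TRIzol and its integrity was assessed before library construction, per the labels' protocols. Base calls were handled with CASAVA, reads were aligned with HISAT2 2.0.5 and genes were counted with featureCounts 1.5.0-p3 on mm10, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. The authors deposited raw read counts per gene for 54532 genes, with symbol, coordinates, length and biotype per the file headers. They also deposited FPKM values for the same genes and libraries, which equal the count divided by gene length and by 1 constant per library. That constant lay 0.13% to 0.66% above the sum of the listed counts. Columns were matched to samples by their letter (A or C) and number. Of the gene identifiers 54409 were found in GENCODE M21, which served for transcript sequences and exon overlaps. The coordinates printed are those of the deposited table.

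The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), which kept 15420 genes and 99.8% of the counts, scaled by TMM, and tested with the quasi-likelihood F-test for the group term with no covariate. Adjusted p-values are Benjamini-Hochberg values called under 0.05, and a standard error is the absolute log2 fold change divided by the square root of F. CPM values are normalised by TMM and given as mean ± SD. Beyond edgeR, gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, over the 29 of 32 lists with at least 5 tested members. For each list the number of members adjusted over the list alone is given too. The lists were chosen for the cell line, the compound, serum withdrawal, RNA quality and other brain cell types. Shares and totals were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1.

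The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 10 protein-coding genes of smallest p when fewer than 5 genes were called, the 3 members of smallest p in each list with called lists first and at most 30 written out, and a fixed set in every case, of which Gnrh1, Kiss1r, Hspa5, Ddit3, Sqstm1, Atp2a2 and Mki67 are given. Some genes that the rule takes are not reported here. Alternatives were DESeq2 size factors, no scaling beyond the total, no filter, a stricter filter, the replicate number as a block, each library left out, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter at FPKM 1 in 3 libraries or none, glmTreat against a fold of 1.2, a correlation estimated per list, and fry. Sample quality weights, a length correction (a loess curve of each library on gene length, span 0.3, removed as an offset) and that correction without control replicate 1 were added after the data were seen.

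Replicates of a group were compared by a chi-square over genes with at least 20 counts in the pair. It was 1.97 to 11.9 per degree of freedom, so no pair differed by less than sampling noise. Named genes were searched with blastn against M21 transcripts for copies of at least 97% identity over at least 100 bases in other genes. The fits were tested on simulated data with 200 genes changed. In this comparison, on 15193 genes, edgeR called 22.4% of genes changed 1.25-fold, 78% of those changed 1.5-fold and 93.9% of those changed 3-fold, with 13 unchanged genes called. Known changes were also thinned into the real counts in 5 runs of 200 genes, which gives the shares in the report. Intervals cover the spread between libraries, and reads without molecular identifiers are not independent molecules.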

Results

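The data were RNA-seq gene counts from GT1-7 cells, a mouse hypothalamic line immortalised with a viral T antigen and used as a model of neurons making gonadotropin-releasing hormone (GnRH). The question set by the design was how Alisol B, a triterpenoid from Alisma rhizome, alters gene expression in these cells. The cells were kept without serum for 12 h and then cultured for 24 h with 0.125 µM Alisol B (3 libraries) or without it (3 control libraries). The total count ranged from 13364102 to 15875638 in the treated and from 13856608 to 15143826 in the control libraries (exact permutation p = 0.9 for the difference). The labels number the replicates but do not say that they were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

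No single gene of the 15420 tested was called higher or lower after Alisol B. The smallest adjusted p was 0.51 in edgeR's quasi-likelihood test, 1501 genes (795 higher, 706 lower) had an unadjusted p under 0.05 where 771 would be counted by chance, and DESeq2 called 0 genes with 949 at an unadjusted p under 0.05. All 10 protein-coding genes of smallest p had that same adjusted p of 0.51, and their values follow with no call attached. Rps27a, which encodes a ribosomal protein fused to ubiquitin (chromosome 11, 29545846 to 29548109, mm10), was at 91.8 ± 3.96 CPM (SD, n = 3) in treated and 170.2 ± 49.4 CPM in control libraries, a log2 fold change of -0.89 (SE 0.16). The control counts of Rps27a ranged from 1743 to 2965, and 4 near-identical gene copies each spanning at least 50% of its transcript could share its reads. The sum of Rps27a and these copies had a log2 ratio of -0.77. Gnrhr, the receptor for GnRH itself (chromosome 5, 86180754 to 86197901), was at 59.9 ± 3.99 CPM after Alisol B and 46.9 ± 3.01 CPM in controls, a log2 fold change of 0.35 (SE 0.07). Faap100, a member of the Fanconi anemia core complex, had a log2 fold change of -0.32 (SE 0.06), and Cyb561d2 had -0.34 (SE 0.07). Ndufaf2, an assembly factor of mitochondrial complex I, had -0.43 (SE 0.09). Among the genes with higher values were Acot11, an acyl-CoA thioesterase, at 0.57 (SE 0.12), and Inpp4b, a phosphoinositide phosphatase, at 0.52 (SE 0.11). Synpo, which encodes an actin-binding protein, had 0.46 (SE 0.09), Samd12 had 0.44 (SE 0.10) and Sorl1, a sorting receptor of the endosome, had 0.39 (SE 0.09). Exons of Acot11, Ndufaf2, Rps27a and Sorl1 overlap those of another gene on the opposite strand, and whether the counting used strand is not given in the sources used here.

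The precision was high enough to bound most abundant genes. Of 6955 genes above 32 CPM, 6867 (98.7%) had a 95% interval that excluded a change of 1.5-fold in either direction. Known changes were also thinned into 200 genes per run, drawn from all genes tested and not only from those above 32 CPM. The same test called 56.4% of genes changed 1.5-fold, 70.4% of those changed 2-fold and 84.4% of those changed 3-fold. With so many genes changed the adjusted p threshold is easier to pass, so these shares do not give the power for a few changed genes. Without control replicate 1, the library that stood apart from the others, 51 genes were called (36 higher, 15 lower). The thinning test without that library also called 756 genes that had not been thinned over 5 runs, against 23 with all 6 libraries. These can include genes already among the 51, but the 51 are too few to make up the 756 even if called in every run. How many of the other calls were false was not tested. Rps27a was lower among the 51 (-0.69, adjusted p = 0.00024 in edgeR and 0.16 in DESeq2), and it was the 1 gene called without control replicate 2 (-1.10, adjusted p = 0.00087). The 1 gene called without control replicate 3 was Ndufa12, a complex I subunit named after its value was seen (-1.35, adjusted p = 0.0017). With 6 libraries Ndufa12 had a log2 fold change of -1.03 (adjusted p = 0.51), and its level was at most 19.9 CPM after Alisol B and 45.8, 43.9 and 18.3 CPM in control replicates 1, 2 and 3.

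**Figure D1:**
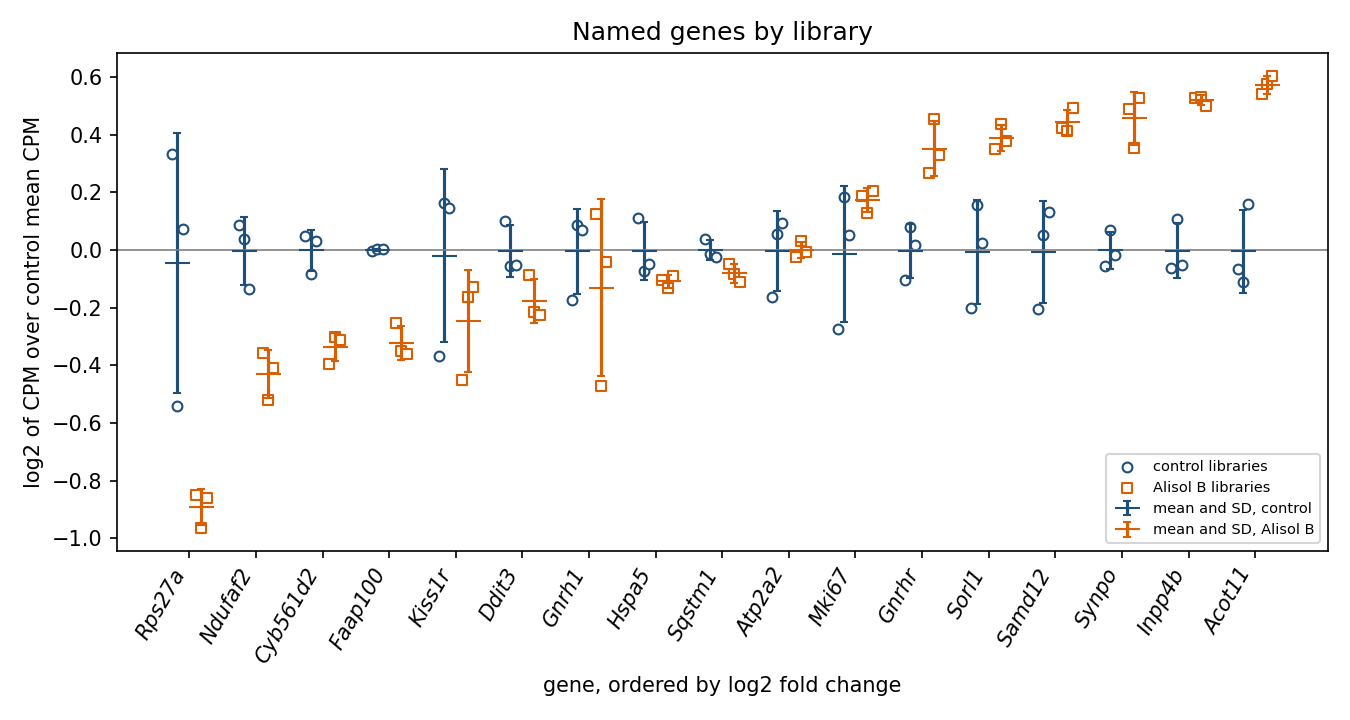
The log2 of each library's CPM over the control mean is plotted for the 10 genes of smallest p and the 7 reported genes of the fixed set, with circles for control and squares for Alisol B libraries and bars for the mean and SD (n = 3). The treated libraries lie beyond all 3 controls for Rps27a, Gnrhr and the other 8 genes of smallest p, and the groups overlap for Gnrh1, Kiss1r, Atp2a2 and Mki67.

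Genes of the endoplasmic reticulum (ER), of the ATF4 stress response and of autophagy and lysosomes were slightly lower as groups after Alisol B. Of 23 ER chaperone and unfolded protein response genes, 19 had lower values and the median log2 fold change was -0.08, a difference of -5.55% (camera adjusted p = 0.0034, and 0.47 with an estimated correlation). Of 34 ATF4 targets 26 had lower values (median -0.08, adjusted p = 0.0034), and of 45 autophagy and lysosome genes 32 did (median -0.07, adjusted p = 0.0034). None of the 3 calls was kept with a correlation estimated per list (adjusted p = 0.47 for each), and no member passed over all genes tested or when adjusted over the list alone. In each of these 3 lists the median of all 3 treated libraries lay below that of every control, and control replicate 1 lay highest, by 0.10, 0.09 and 0.06 above the mean of the 6 libraries. The ER members of smallest p were Creld2, at 175.4 ± 4.70 CPM after Alisol B and 209.5 ± 21.7 CPM in controls (log2 fold change -0.26, SE 0.07), Sdf2l1 at -0.28 (SE 0.08) and Hsp90b1, the chaperone GRP94, at -0.17 (SE 0.06). Hspa5, the chaperone BiP and a main reporter of ER stress, had a log2 fold change of -0.11 (SE 0.06, adjusted p = 0.53 in edgeR), and -0.05 without control replicate 1, where Creld2 had -0.17 and Hsp90b1 had -0.11. Among ATF4 targets, Nupr1 had -0.28 (SE 0.07), Chac1, a glutathione-degrading enzyme, had -0.18 (SE 0.06) and Atf4 itself had -0.17 (SE 0.06). Ddit3, the stress-induced transcription factor CHOP, was at 66.1 ± 3.55 CPM after Alisol B and 74.6 ± 4.74 CPM in controls (-0.17, SE 0.07, adjusted p = 0.51). Among autophagy and lysosome genes, Atg5 had -0.22 (SE 0.07), and the lysosomal hydrolases Gla and Neu1 had -0.19 (SE 0.07) and -0.15 (SE 0.05). Sqstm1, the autophagy receptor p62, had -0.08 (SE 0.05, adjusted p = 0.57). Without control replicate 1 all 3 lists were still called (adjusted p = 0.00090 for each, and 0.53 for each with an estimated correlation), with the ER median at -0.05, and without control replicate 2 the ER median was -0.13 (adjusted p = 0.0065).

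Heat shock and NRF2 antioxidant genes were also called lower, with less margin. Of 15 heat shock genes 12 had lower values (median -0.07, camera adjusted p = 0.022, and adjusted p = 0.64 with an estimated correlation), with Hspe1 at -0.18 (SE 0.07), Chordc1 at -0.13 (SE 0.06) and Dnaja1 at -0.12 (SE 0.06). Of 25 NRF2 and antioxidant genes 21 had lower values (median -0.09, adjusted p = 0.016, and 0.64 with an estimated correlation), among them the ferritin chains Fth1 at -0.20 (SE 0.08) and Ftl1 at -0.17 (SE 0.07) and glutathione reductase, Gsr, at -0.15 (SE 0.06). Of these genes, Fth1 and Ftl1 had -0.08 each, Hspe1 had -0.10 and Dnaja1 had -0.07 without control replicate 1. Control replicate 1 lay highest in both lists, by 0.10 and 0.13 above the mean of the 6 libraries, and no member of either list passed over all genes tested or adjusted over the list alone. Both calls ended without control replicate 1 (medians -0.05 and -0.03, adjusted p = 0.11 for each), the NRF2 call also after a correction for gene length (median -0.05, adjusted p = 0.0501), and the heat shock call also ended without control replicate 3 (adjusted p = 0.067), without Alisol B replicate 1 (adjusted p = 0.057), without Alisol B replicate 3 (adjusted p = 0.16) and with the replicate number as a block (adjusted p = 0.051).

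The lists with the smallest p were cytosolic ribosomal proteins and the nuclear-encoded subunits of oxidative phosphorylation. Both were called lower after Alisol B with all 6 libraries, but the ribosomal difference rested on control replicate 1. Of 85 ribosomal protein genes 82 had lower values (median log2 fold change -0.12, camera adjusted p = 2.6e-07), and of 41 oxidative phosphorylation genes 40 did (median -0.12, adjusted p = 2.2e-06). Both calls were lost with an estimated correlation (adjusted p = 0.64). Control replicate 1 moved with these lists: ribosomal protein genes took 3.85% of its counts, against 3.10% and 3.15% in the other 2 controls and 3.10% ± 0.04 (SD, n = 3) in the treated group. The difference between the groups in this share was smaller than the spread allowed to resolve (exact permutation p = 0.2, where 3 against 3 cannot go below 0.1, and adjusted p = 1 over 5 shares and totals). Without control replicate 1 the ribosomal median was -0.0058 (adjusted p = 0.33), and the oxidative phosphorylation median was -0.04 (adjusted p = 0.021, and 0.59 with an estimated correlation). After the length correction both were at -0.06 (adjusted p = 0.0029 and 0.0017), and with both changes the oxidative phosphorylation call ended too (adjusted p = 0.28). Rpl38 had a log2 fold change of -0.28 (SE 0.09) and Rps2 had -0.20 (SE 0.07), and 15 near-identical gene copies each spanning at least 50% of its transcript could share reads of Rps2. In the ribosomal list 1 gene, Rps27a, passed when adjusted over the list alone, and none of the oxidative phosphorylation genes did. The latter of smallest p were the complex II subunits Sdhc at -0.20 (SE 0.06) and Sdhd at -0.19 (SE 0.06) and the complex IV subunit Cox4i1 at -0.19 (SE 0.07). Rpl38 had -0.15, Rps2 had -0.10 and Cox4i1 had -0.09 without control replicate 1. Of 13 mRNAs encoded by the mitochondrial genome 9 had higher values, and the list was not called (median 0.11, adjusted p = 0.25), although it was after the length correction (median 0.17, adjusted p = 0.0069) and with sample quality weights (median 0.10, adjusted p = 0.0020). It was also called with that correction without control replicate 1 (median 0.16, adjusted p = 0.036), but not without that library by itself (adjusted p = 0.11). With an estimated correlation its adjusted p was 0.64 with 6 libraries and 0.59 without control replicate 1. The median was 0.05 without Alisol B replicate 2 or control replicate 2 and 0.06 without Alisol B replicate 1. In this list mt-Co2, a subunit of complex IV, passed when adjusted over the list alone (1.37, SE 0.33), and a near-identical gene copy matching 99.6% of its transcript could share its reads. It averaged 99.8 CPM in treated and 38.3 CPM in control libraries, against 14373 and 13750 CPM for mt-Co1 of the same complex. A copy matching 99.6% of its transcript could also share reads of mt-Atp6 (467 to 2193 counts per library). The list was tested without adding such copies. Counts from the mitochondrial chromosome took 3.06% ± 0.03 of the treated and 3.03% ± 0.13 of the control libraries (SD, n = 3, exact permutation p = 0.7).

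Voltage-gated channel genes and genes that govern puberty and GnRH secretion were called higher as groups after Alisol B with all 6 libraries. Both medians shrank without control replicate 1 and after the length correction. Of 26 channel genes 23 had higher values (median 0.17, camera adjusted p = 2.2e-05), and of 26 puberty and GnRH-secretion genes 20 did (median 0.13, adjusted p = 0.0034). Both calls were lost with an estimated correlation (adjusted p = 0.64). In the second list 3 genes passed when adjusted over the list alone, all with higher values, among them Gnrhr and the progesterone receptor gene Pgr. Pgr was at 60.2 ± 3.98 CPM after Alisol B and 44.3 ± 7.52 CPM in controls (0.44, SE 0.11). In the channel list 1 gene passed when adjusted over the list alone, Cacna1h, the pore subunit of a low-threshold T-type calcium channel, at 122.7 ± 5.01 CPM and 93.1 ± 13.4 CPM (0.40, SE 0.09). Cacna2d1, an auxiliary calcium channel subunit, had 0.19 (SE 0.06). Kcnj11, a subunit of the ATP-sensitive potassium channel, had 1 to 20 counts per library, and its log2 fold change of 1.72 (SE 0.55) rests on these (1.30 to 2.77 when each library was left out). With 6 libraries none of these genes passed over all genes tested (adjusted p = 0.51). Gnrhr, Pgr and Cacna1h passed in edgeR without control replicate 1 (adjusted p = 0.040, 0.036 and 0.0046). In DESeq2 without that library Cacna1h passed (adjusted p = 0.0042), but Gnrhr (0.078) and Pgr (0.072) did not. With a length correction as well, edgeR did not call Pgr (adjusted p = 0.059). The same genes passed with no filter on low counts (adjusted p = 0.0080, 1.6e-04 and 7.2e-05), in a fit that pooled all genes to a common spread. Genes of both lists are long (median 10.3 kb for the channel list and 8.23 kb for the puberty list, against 3.94 kb for all genes tested). Control replicate 1 lay lowest in both lists, with medians of -0.26 and -0.22 from the mean of the 6 libraries. Without that library the channel median was 0.07 (adjusted p = 0.0026, and 0.53 with an estimated correlation) and the puberty median 0.05 (adjusted p = 0.20). After a length correction the channel median kept 0.36 of its size, and the medians were 0.06 (adjusted p = 0.014) and 0.04 (adjusted p = 0.21), and with both changes the channel call ended too (median 0.04, adjusted p = 0.15).

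The secreted hormone and its main input had low levels. Gnrh1, which encodes GnRH, stood at percentile 10.9 of the genes tested and had 15 to 24 counts per library, or 1.29 ± 0.26 CPM after Alisol B and 1.39 ± 0.14 CPM in controls (SD, n = 3). Its log2 fold change was -0.11 (SE 0.28, 95% interval -0.73 to 0.51, adjusted p = 0.90), so a change within that interval was not detectable at these counts. The identity of the line was not analysed here. Kiss1r, the kisspeptin receptor, had 36 to 56 counts per library and a log2 fold change of -0.25 (SE 0.21, adjusted p = 0.67), with a range of -0.40 (without control replicate 1) to -0.15 (without Alisol B replicate 1) when each library was left out. Of 17 transcription factors of GnRH neurons 9 had higher values (median 0.01, adjusted p = 0.41), and of 25 peptide-processing and dense-core vesicle genes 16 had lower values (median -0.04, adjusted p = 0.43, and -0.0085 without control replicate 1). Neither list was called.

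Sterol genes and the cell cycle gave no call. Of 25 cholesterol synthesis and uptake genes 17 had lower values (median -0.05, camera adjusted p = 0.090). This list was called without control replicate 1 (median -0.06, adjusted p = 0.023), without Alisol B replicate 2 (median -0.09, adjusted p = 0.0092) and with sample quality weights (median -0.06, adjusted p = 0.00063). It was also called with the length correction without control replicate 1 (median -0.06, adjusted p = 0.036), but not with that correction and 6 libraries (adjusted p = 0.062). With an estimated correlation the adjusted p was 0.64 with 6 libraries and 0.67 without control replicate 1. Of 35 calcium store and calcium signalling genes 19 had higher values (median 0.03, adjusted p = 0.25, and 9.4e-04 without control replicate 1). Atp2a2, the ER calcium pump, was at 682.7 ± 13.5 CPM after Alisol B and 682.7 ± 63.8 CPM in controls (95% interval of the log2 fold change -0.15 to 0.15). Of 30 S phase genes 23 had lower values (median -0.03, adjusted p = 0.10), and this list was called without control replicate 2 (adjusted p = 0.046). With an estimated correlation and 6 libraries its adjusted p was 0.64, and its median without control replicate 1 was -0.02 (camera adjusted p = 0.33). Of 30 G2 and M phase genes 20 had lower values (median -0.03, adjusted p = 0.25), and the median ranged from -0.05 to -0.01 when each library was left out. Mki67, a proliferation marker, was at 1650.6 ± 47.1 CPM and 1462.9 ± 231.5 CPM (0.17, SE 0.09, adjusted p = 0.53), and its log2 fold change was 0.05 without control replicate 1.

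Other signalling and metabolic lists were not called. Their medians were 0.08 for TGF-beta, YAP and extracellular matrix genes (17 of 21 higher, adjusted p = 0.10), 0.08 for circadian clock genes (12 of 17 higher, adjusted p = 0.15) and 0.07 for PI3K, mTOR and FoxO genes (20 of 29 higher, adjusted p = 0.12). The clock median was 0.02 and the PI3K median 0.04 without control replicate 1. Immediate early and MAPK feedback genes had a median of 0.03 (adjusted p = 0.41), p53 targets and apoptosis genes 0.01 (adjusted p = 0.53), and fatty acid synthesis and LXR targets 0.01 (adjusted p = 0.48). In 3 lists the median, the mean and the test differed in sign. Interferon response genes had a median of 0.02 and a mean of -0.02 (test up, adjusted p = 0.48), glycolysis and hypoxia genes a median of -0.02 and a mean of 0.02 (test down, adjusted p = 0.56), and NF-kB and inflammatory genes a median of 8.6e-05 and a mean of -0.04 (test down, adjusted p = 0.70). The 5 replication-dependent histone genes tested had a median of -0.22 (adjusted p = 0.15), and with no filter on low counts the list median was -0.02 (adjusted p = 0.82). Hist1h1c, a linker histone gene, passed when adjusted over that list alone (-0.32, SE 0.09). Of the bile acid receptor FXR and its targets 4 genes reached the depth for testing, and the list was not tested.

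Few markers of other cell types reached the depth for testing. Of 13 oligodendrocyte markers 5 were tested, all 5 with higher values after Alisol B (median 0.24, camera adjusted p = 0.022, and 0.47 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Among those of smallest p were Pdgfra, at 9.49 ± 1.07 CPM after Alisol B and 8.03 ± 1.15 CPM in controls, and Cspg4, with a log2 fold change of 0.41 (SE 0.28), which ranged from 0.25 to 0.74 when each library was left out. That of Pdgfra was 0.24 and ranged from 0.12 to 0.33. The most abundant, Mbp, had a log2 fold change of 0.0056 (SE 0.07). This call ended without control replicate 1 (adjusted p = 0.11), without control replicate 3 (adjusted p = 0.11), without Alisol B replicate 3 (median 0.15, adjusted p = 0.059), with sample quality weights (adjusted p = 0.12) and after the length correction (adjusted p = 0.085). Astrocyte markers (6 tested, median -0.02, adjusted p = 0.70) and endothelial markers (5 tested, median 0.14, adjusted p = 0.33) were not called. Kdr, a receptor for vascular endothelial growth factor, passed when adjusted over the endothelial list alone (0.23, SE 0.07). Of microglia markers 2 were tested and of fibroblast and pericyte markers 3, too few for a list test.

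**Figure D2:**
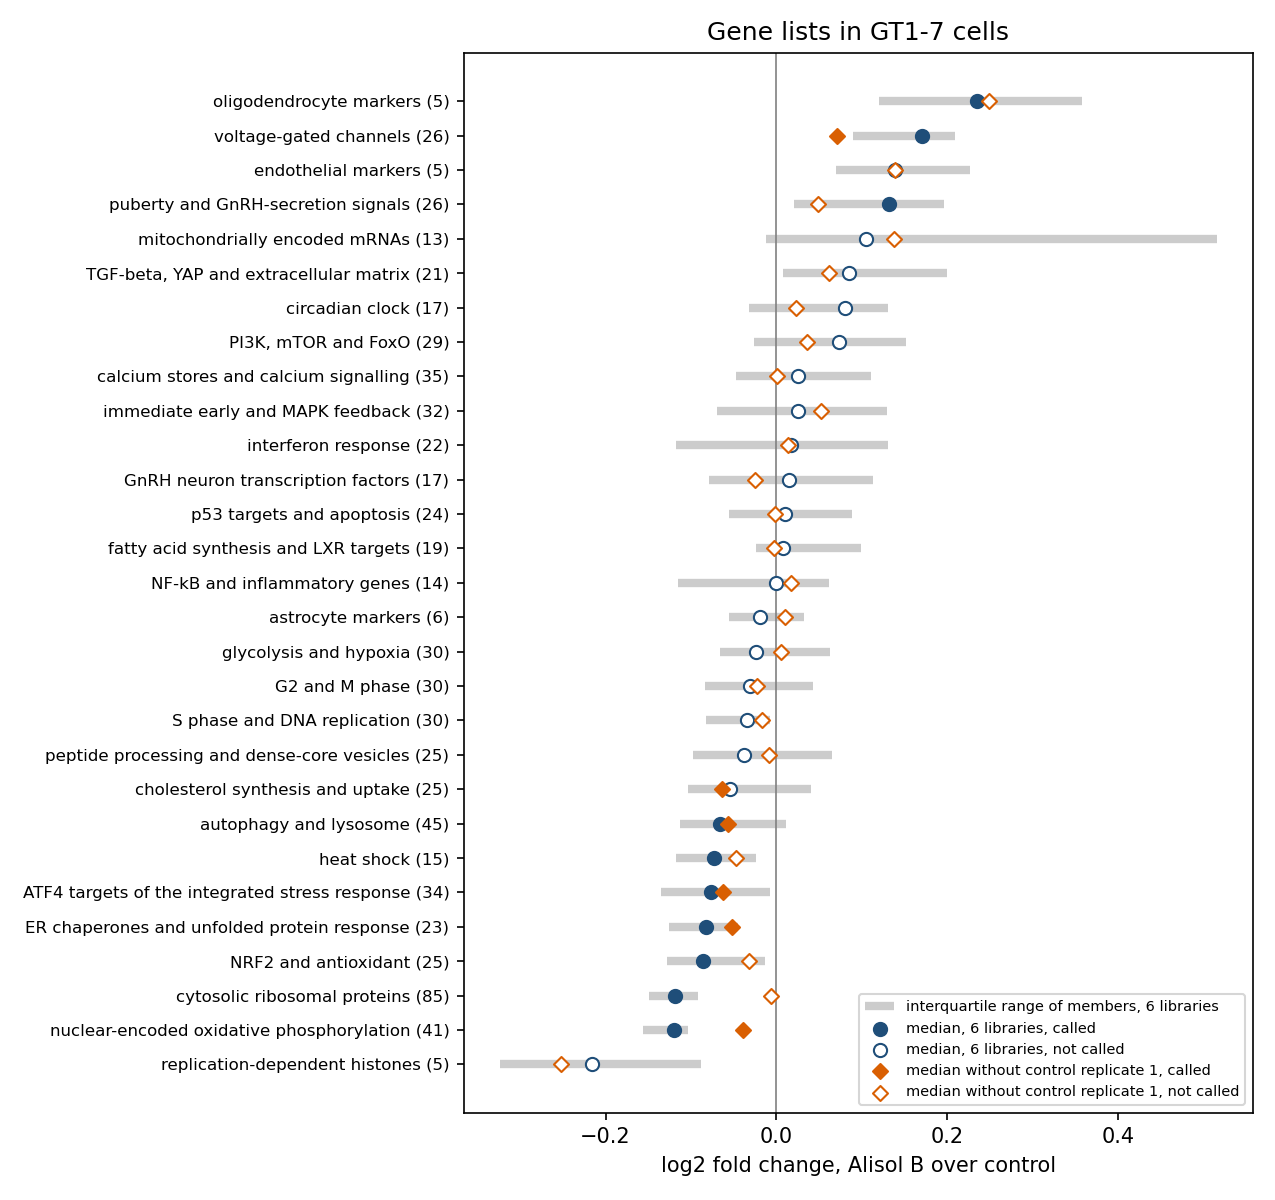
The median log2 fold change of each list with at least 5 tested genes (number in brackets) is plotted for all 6 libraries (circles) and without control replicate 1 (diamonds), filled where camera called the list and with grey bars for the interquartile range of its members. The ribosomal median lies at -0.12 with all libraries and at -0.0058 without that control, while the autophagy and lysosome median lies at -0.07 and -0.06.

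Control replicate 1 differed from the other 5 libraries. It lay at 35.5 on the first principal component (36.3% of the variance), while the others lay between -11.8 and -1.73. Short genes were higher and long genes lower in it, with a Spearman correlation of -0.42 across genes between its deviation from the other libraries and gene length. The same correlation was 0.17, 0.22 and 0.22 for Alisol B replicates 1, 2 and 3, and 0.06 and 0.04 for control replicates 2 and 3, so it also differed between the groups. Genes are not independent replicates, so no p is given.

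**Figure D3:**
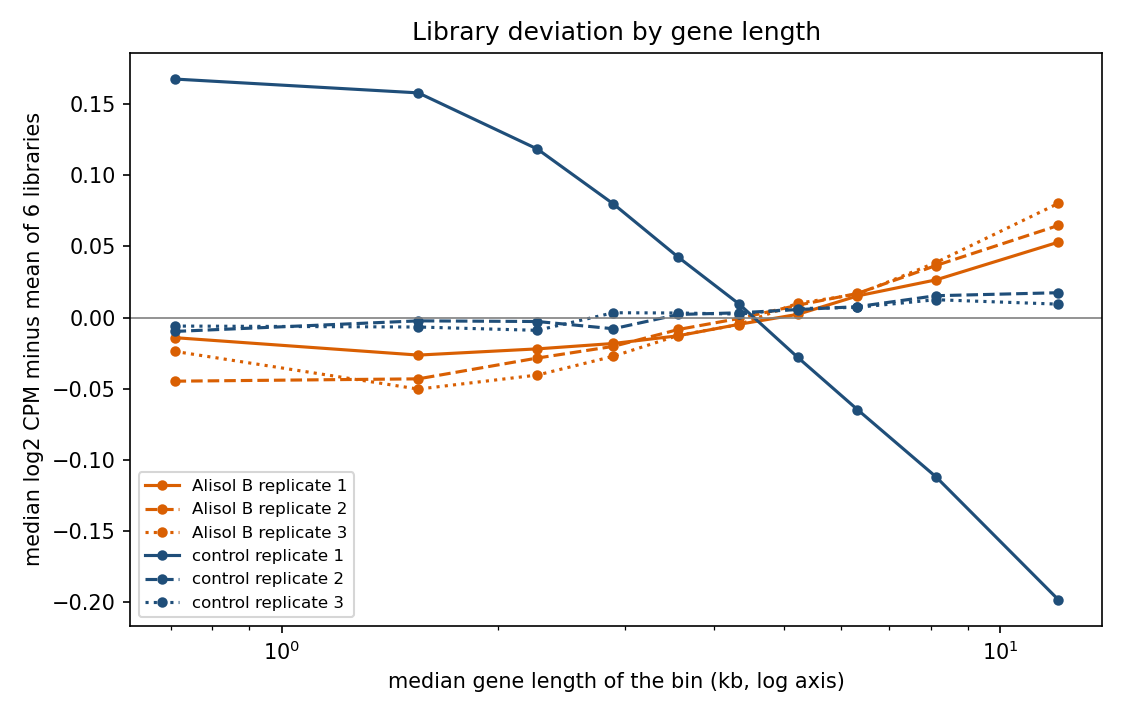
The median deviation of each library from the mean of all 6, in log2 CPM, is plotted for 10 bins of 1542 tested genes each by gene length (log axis, kb). Control replicate 1 runs from 0.17 in the shortest bin to -0.20 in the longest. In the longest bin the 3 Alisol B libraries lie between 0.05 and 0.08, and control replicates 2 and 3 at 0.017 and 0.0095.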

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

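The alternatives with sample quality weights and with the length correction were chosen after seeing the data. The count of 0 genes was also found with DESeq2 size factors, total scaling, the stricter filter, DESeq2, the 3 FPKM fits, an adjusted p of 0.01 or 0.1 and glmTreat (for a size limit). With no filter, 213 genes were called (174 higher, 39 lower, 13 at least 2-fold). Of these, 212 were among the genes tested with the filter, and they included Rps27a, Gnrhr, Pgr and Cacna1h. In that fit the prior pooled all genes to a common spread (total degrees of freedom 123016 against a median of 11.4). Sample quality weights gave 3 genes (Rev3l higher, Rps27a and Faap100 lower, so 1 higher and 2 lower), with a weight of 0.16 for control replicate 1. Leaving out each library gave 0 to 51 genes (0 to 36 higher, 0 to 15 lower, 0 to 1 at least 2-fold), with the 51 without control replicate 1. The length correction without that library gave 25 genes (16 higher, 9 lower, 1 at least 2-fold), of which 20 were shared with the 51. The causes were not tested, except that control replicate 1 raised the spread (coefficient of variation 7.21% with it and 3.77% without).

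The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.06, -0.02 and 0.03. With the number as a block, 0 genes and 9 lists were called, and the heat shock list was at an adjusted p of 0.051. The 10 lists called (3 higher, 7 lower) became 0 (0 higher, 0 lower) with estimated correlations. Fry gave 1 list in a single direction (0 higher, 1 lower), autophagy and lysosome at an adjusted p of 0.022. Its test in either direction, which assigns no direction to a list, gave 1, oligodendrocyte markers (adjusted p = 0.025). In a single direction fry did not call that list (adjusted p = 0.059). Leaving out each library gave 6 to 11 lists (1 to 3 higher, 5 to 8 lower). It moved the median by over 1.5 times at least once in 26 of 29 lists, all but the ATF4, autophagy and TGF-beta lists, and the value of 17 of 43 named genes. The length correction without control replicate 1 gave 5 (1 higher, 4 lower).

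Some values changed sign, most of them near 0, and 2 lists further from 0, the ribosomal (median -0.12) and PI3K (0.07) lists. Atp2a2 was at 0.0021 with DESeq2 size factors, 4.8e-04 with the stricter filter or total scaling, 0.0041 in the block, 0.0012 in DESeq2 and 0.0056 in each FPKM fit. Leaving out each library gave ranges of -0.077 to 0.049 for Atp2a2 and -0.25 to 0.045 for Gnrh1. The ranges of list medians were -0.025 to 0.092 (GnRH neuron factors), -0.049 to 0.051 (NF-kB), -0.15 to 0.047 (astrocyte), -0.0022 to 0.043 (fatty acid), -0.038 to 0.014 (glycolysis), -0.017 to 0.059 (immediate early), -0.013 to 0.029 (interferon) and -0.0013 to 0.037 (p53). With no filter the NF-kB, interferon and astrocyte medians were -0.031, -0.0044 and 0.038. Quality weights gave medians of -0.0041 (GnRH neuron factors), -0.0030 (calcium), -5.1e-05 (NF-kB), 0.0046 (glycolysis) and 0.0018 (astrocyte). The length correction gave medians of -0.0020 (GnRH neuron factors), -0.035 (calcium), -0.0088 (PI3K), -0.0017 (NF-kB) and 9.3e-04 (astrocyte). That correction without control replicate 1 gave medians of -0.024 (GnRH neuron factors), -0.010 (calcium), -0.0012 (fatty acid), -0.0042 (PI3K), 0.0056 (glycolysis), 0.0096 (ribosomal) and 0.024 (astrocyte). The cause was not tested. Over all alternatives, 718 of the named-gene values and 360 of the list medians kept direction and side of the threshold. Of the other named-gene values 13 reversed and 33 passed it anew, and of the other medians 36 reversed, 31 lost the call and 8 gained it. Low counts limit Gnrh1, Kiss1r, Kcnj11 and the cell type markers.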

Other observations

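The tests of gene length and of a wrong label for control replicate 1, and of that library alone for the list calls, were chosen only after the result was seen. The genes named in the next sentences were also chosen after their values were seen. Without control replicate 1, the called genes with higher values after Alisol B included Rev3l, the catalytic subunit of a translesion DNA polymerase (log2 fold change 0.27, SE 0.04, adjusted p = 0.00030 in edgeR), Lrp1, an endocytic receptor (0.26, SE 0.04), Irs4, an insulin receptor substrate (0.17, SE 0.03), Ngfr, the p75 neurotrophin receptor (0.37, SE 0.08), Cdkn1b, the cell cycle inhibitor p27 (0.18, SE 0.04), and Cacna1h, Gnrhr and Pgr. Those with lower values included 2 genes of dense-core vesicles, Ptprn (-0.15, SE 0.03) and Vgf (-0.16, SE 0.03), the ER gene Creld2 (-0.17, SE 0.04), the threonyl-tRNA synthetase gene Tars (-0.13, SE 0.03), Sirt7 (-0.30, SE 0.06) and Rps27a. DESeq2 without that library called 29 genes, 21 of them among the 51. Of the genes named here it called Rev3l, Lrp1, Irs4, Cdkn1b, Cacna1h, Ptprn, Vgf and Tars, but not Rps27a (adjusted p = 0.16), Gnrhr (0.078), Pgr (0.072), Creld2 (0.076) or Sirt7 (0.096), and it gave no adjusted p for Ngfr. After the length correction 20 of the 51 were called, among them Rev3l, Cacna1h, Gnrhr, Ngfr, Irs4, Cdkn1b, Ptprn, Tars and Rps27a, but not Lrp1, Pgr, Vgf or Creld2.

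mt-Co2, the complex IV subunit, varied among the treated libraries, with 1378, 699 and 2216 counts in the 3 Alisol B libraries and 498, 526 and 660 in the controls (log2 fold change 1.37, SE 0.33, adjusted p = 0.51 with 6 libraries, and without control replicate 1 adjusted p = 0.020 in edgeR and 0.51 in DESeq2). The near-identical gene Gm28661 matches 99.6% of its transcript and could share its reads, and the sum of both was 1826, 900 and 2462 against 749, 773 and 837.

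The first pattern is control replicate 1 itself. Its deviation from the other libraries followed gene length (Spearman -0.42 across genes), which makes a bias by length, from RNA integrity or library making, a candidate explanation. GC content adds little (partial correlation -0.052 given length, against -0.42 for length given GC). A treated library under a control label is argued against over the 25 genes called without it after the length correction. Its median position over these was -0.068, where 0 is the other 2 controls and 1 the treated libraries (quartiles -0.68 and 0.33). Of the 25 genes, 19 put it nearer the controls. Its correlations with treated libraries (0.987 to 0.988) and with other controls (0.988 to 0.989) lay close together. For that reason the position replaced an earlier measure, and both were set after the data were seen. What made the length trend stays open, and no biological explanation was tested. A smaller trend was left without it (Spearman 0.16 between the log2 fold change and gene length, against 0.35 with all 6).

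The second pattern is the lower ribosomal protein and oxidative phosphorylation lists. Control replicate 1 may account for the first: the ribosomal median kept 0.049 of its size without that library, while the oxidative phosphorylation median kept 0.32 and stayed called by camera (adjusted p = 0.59 with an estimated correlation). The length correction left 0.48 and 0.53 of the medians with both lists called. With both changes the shares kept were -0.08 (a reversed sign) and 0.14, at medians of 0.0096 and -0.017. By itself the ribosomal list met the limit, set after the result was seen, for control replicate 1 alone (median -0.0058, camera adjusted p = 0.33 without it). The oxidative phosphorylation list did not meet it. On gene length the lists lay on opposite sides of the 0.5 set beforehand. The limits were set for the pair of lists, for which neither explanation can be told apart from the treatment. For the ribosomal list by itself the difference between the groups rested on control replicate 1. Its medians from the mean of the 6 libraries were -0.037, -0.065 and -0.066 in Alisol B replicates 1, 2 and 3. They overlapped those of control replicates 2 and 3 (-0.057 and -0.034), while control replicate 1 was at 0.26.

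The third pattern is the lower ER chaperone, ATF4 target and autophagy-lysosome lists. Control replicate 1 as the whole cause is argued against, since the medians kept 0.63, 0.81 and 0.85 of their size without it. All 3 lists also stayed called by camera at the preset correlation. The limit for this was set after the result was seen, and the ER share lay just above it. Gene length as the whole cause is argued against too, since the medians kept 0.83, 0.79 and 0.77 after the correction with all 3 called. With both changes they kept 0.596, 0.78 and 0.90, which put the ER share just under the limit for control replicate 1. These calls rest on camera at the preset correlation, which also called 2 to 6 lists in every other split of the libraries. A small lowering of these stress and lysosome genes by Alisol B is therefore only a hypothesis, found and tested on the same data. The estimated-correlation test did not call it (adjusted p = 0.53 without control replicate 1).

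For the higher voltage-gated channel list, the length correction left 0.36 of the median, below the 0.5 set before the result was seen as the mark of gene length, with the list still called (adjusted p = 0.014). Its adjusted p with an estimated correlation was 0.64 with 6 libraries and 0.53 without control replicate 1, and the camera call ended with the correction and without that library together (adjusted p = 0.15). Rps27a with its near-identical copies had a log2 ratio of -0.77, against -0.89 for Rps27a by itself.

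The 6 libraries make 10 splits into 3 against 3, too few to give a share under 0.05. The real split gave 0 genes and the highest of the others 2, so all 10 gave as many. For genes changed at least 2-fold it gave 0 and the highest other 1, again with all 10 as many. For lists the real split gave 10 calls, so 1 split, the real one, gave as many. Each of the other splits also gave called lists, from 2 to 6, so camera at the preset correlation called lists in wrong groupings too. At an unadjusted p under 0.05 the real split gave 1501 genes and the highest other 640.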
